A study of Mus musculus with 12 samples.

How the data were processed

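RNA from AML12 cells, a mouse hepatocyte line, was sequenced in 12 libraries that form 4 groups of 3. Cells received a GFP plasmid or a GFP-DUSP6 plasmid and were collected 24 h later, or received a negative-control siRNA (NC) or an siRNA against Dusp6 (siDUSP6) and were collected 48 h later. The groups and replicate numbers come from the sample titles. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Counts of every pair of replicates differed by more than sampling noise (chi-square per degree of freedom between 3.89 and 25.7, genes with a summed count above 10).

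The authors deposited 1 table per contrast with whole-number counts per gene and library. Per the submitters' processing notes the fold changes come from DESeq2 and the genome build is mm10; the versions, the aligner, the counting tool and the annotation are not given in the sources used here. Per the file headers the deposited tables also hold a log2 fold change, a p-value and an adjusted p-value per gene, and the siRNA table also holds the authors' mean normalized signal per gene and the linear fold (ratio). Each deposited table holds a selected part of the genes: 707 genes in the plasmid table and 2150 in the siRNA table. These are the genes with an adjusted p under 0.05, and further genes without an adjusted p (127 and 191) whose p-values in the deposited tables reach at most 0.0500 and 0.0499. The adjusted p, the rank and the p of the deposited rows imply 12592 tested genes in the plasmid contrast and 13102 in the siRNA contrast (505 and 1645 rows within 0.01 of the whole number), and the relation held up to the last called rank, so that no called gene is missing. Genes that did not pass cannot be examined here.

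Because only selected genes are listed, a new test on them cannot discover genes. A gene is called here where its adjusted p in the authors' deposited table is under 0.05, as laid down for this case before the data were examined. The size factors of the whole libraries were recovered, in the siRNA contrast from the deposited mean normalized signal and in the plasmid contrast from the deposited fold changes of 489 genes with more than 200 counts in each library (largest error 0.00065 on the log2 scale). They lay between 0.94 and 1.05 in the plasmid contrast and between 0.951 and 1.04 in the siRNA contrast. Counts divided by them are the normalized counts given as mean ± SD over 3 libraries. Log2 fold changes ± SE come from an edgeR quasi-likelihood refit with these size factors (edgeR 4.0.16, R 4.3.3, filterByExpr with a minimum count of 10). The dispersion of that refit rests on listed genes, and its SE had a median of 0.848 (plasmid) and 0.89 (siRNA) times the SE implied by the deposited p. Refit p-values were adjusted by Benjamini-Hochberg over the implied number of tested genes.

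The refit was tested on simulated counts with 200 changed genes and a dispersion of 0.01. With changed genes drawn from those with a mean of at least 50, it recovered 72.9% of log2 changes of 0.5 in the plasmid contrast (707 genes) and 60.3% in the siRNA contrast (2150 genes), and 100% of changes of 1 and of 2 in each. That minimum was set after a first simulation failed on genes with few counts. With changed genes drawn from every level, 80.6% (plasmid) and 93.2% (siRNA) of changes of 2 were recovered. The simulated dispersion was not estimated from these libraries. Most simulated genes were unchanged, and rises and falls were equally likely. The listed genes were selected as changed, so these percentages describe the simulated setting and not the calls reported here.

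Members of 29 gene lists, written before the data were examined, were matched by identifier. For each list with at least 3 called members, Fisher's exact test (two-sided) compared its split into higher and lower with that of the other called genes, with Benjamini-Hochberg adjustment over the lists. That test says how called members divide and not whether many were called; a one-sided hypergeometric test of the number called, which takes every member as tested, was added after the data were seen. Counts adjusted over the list alone take members that are not listed as having a p of 1. Tests against all expressed genes (camera, fry) need the unlisted genes and were not run. Both list tests take genes as independent, which genes that respond together are not. Their p-values thus describe the table of genes and not replicates. For genes called in both contrasts the directions were compared by Fisher's exact test on the table of directions. Named genes were Dusp6, in each contrast the 8 higher and 8 lower called genes with the largest absolute log2 fold change (a mean of at least 50 in the higher group and no overlap between groups), up to 4 called members of each list with the smallest adjusted p, and across contrasts 8 genes with opposite and 4 with the same direction and the largest smaller fold change, under the same conditions of mean and overlap in each contrast. Alternatives were DESeq2 1.42.0, scaling over the listed genes by TMM or median of ratios, no count filter, the replicate number as a block, a threshold of 0.01, a log2 fold change of at least 1, and leaving out each replicate. Coordinates are from GENCODE M21, which uses the same build as mm10; 14 and 24 of the listed identifiers had no match in it. Whether strand was kept is not given in the sources used here, so reads of a gene and of exons on the other strand cannot be told apart; among the named genes this holds for Dusp1, Dusp5, Dusp8, Cxcl10, Irf1, Irf7, Usp18, Ccna2, Cp, Hspa1a and Stab1, among others. Sequence shared with other genes was counted as 50-base words of the annotated transcripts. Fdps, Oas1a and Ccnb1 shared 21.9%, 16.7% and 12.9% of these words with other genes, so their counts cannot be assigned to them with certainty. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.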

Results

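Gene expression was measured by RNA sequencing in AML12 cells, a mouse hepatocyte line, after transfections meant to change the amount of DUSP6. DUSP6 is a phosphatase that removes phosphate from the MAP kinase ERK. One contrast set 3 libraries labelled GFP-DUSP6 against 3 labelled GFP, 24 h after transfection of plasmids. The other set 3 siDUSP6 libraries against 3 negative-control (NC) siRNA libraries, 48 h after transfection. The design asks which genes respond to overexpression and to knockdown of DUSP6. The contrasts share no library, and they differ in time and in the kind of nucleic acid. Counts over the listed genes ranged from 1303866 to 1531091 per library in the plasmid contrast and from 3500977 to 4078892 in the siRNA contrast; these sums cover listed genes only and are not library depths.

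The targeted gene, Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489, plus strand), was lower in the siDUSP6 libraries, at 1783 ± 46.1 normalized counts against 3935 ± 129 in NC (SD, n = 3 each), a log2 fold change of -1.14 ± 0.06 (SE). In the libraries labelled GFP-DUSP6 it was also lower, at 2354 ± 126 against 3352 ± 57.2 normalized counts with GFP (SD, n = 3 each), a log2 fold change of -0.51 ± 0.06 (SE). In the authors' deposited table the adjusted p (DESeq2) was 3.74e-56 for the siRNA contrast and 2.56e-12 for the plasmid contrast. The count thus goes against the label of the plasmid group. Whether a transcript from the plasmid is part of this count is not given in the sources used here, and directions in that contrast are stated for the libraries labelled GFP-DUSP6.

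**Figure D1:**
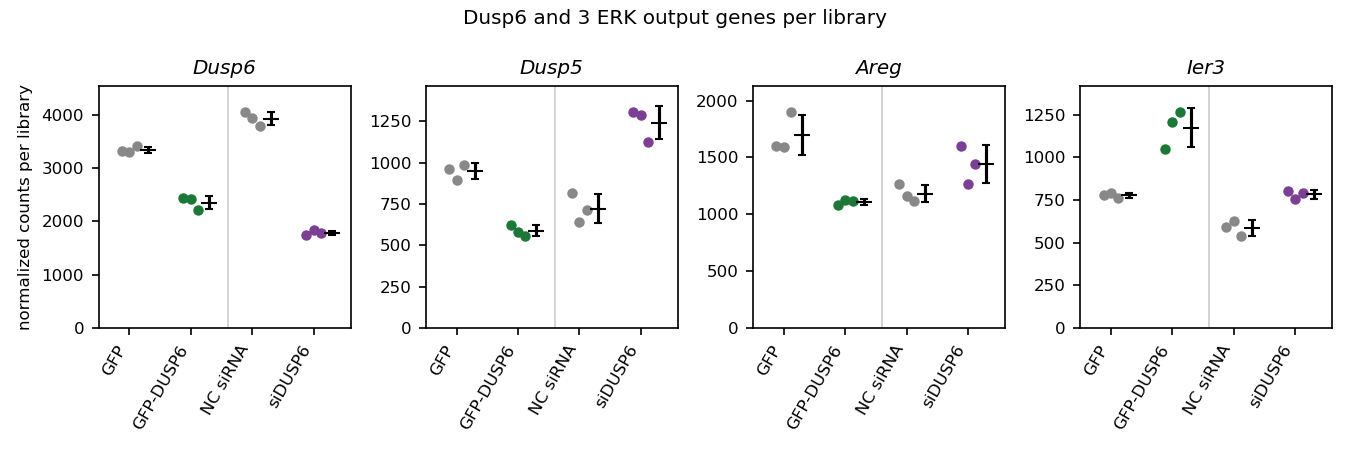
Normalized counts per library (vertical axis, from 0) of Dusp6 and 3 genes of the ERK output list in the 4 groups; points are libraries, the bar beside them is the mean with its SD (n = 3), and the grey line parts the contrasts. Dusp6 had a mean of 2354 with GFP-DUSP6 against 3352 with GFP, and of 1783 with siDUSP6 against 3935 with NC.

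In the libraries labelled GFP-DUSP6, the 8 largest rises among called genes with a mean of at least 50 were chemokine and acute-phase genes. Lcn2, which encodes an iron-carrier binding protein, rose from 69.6 ± 12.4 to 1220 ± 291 normalized counts (SD, n = 3), a log2 fold change of 4.13 ± 0.18 (SE). The chemokine gene Ccl2 rose by 3.33 ± 0.08 on the log2 scale, Cxcl5 by 3.92 ± 0.21, Cxcl1 by 2.35 ± 0.13 and Ccl20 by 2.53 ± 0.22, and Saa3, an acute-phase gene, by 3.16 ± 0.27. Cxcl3 and Cxcl10 complete the 8. Of the 26 members of the NF-kB list, 17 were called higher and 0 lower (split against the other called genes, Fisher's exact adjusted p = 0.0276), with a median log2 fold change of the called members of 1.08, against 1.18 for the interferon list. The falls were smaller: Hspa1b, a heat shock gene, had a log2 fold change of -1.48 ± 0.21 and the ATP receptor gene P2rx7 of -1.29 ± 0.18. Hspa1b and Hspa1a share 62.9% and 59.2% of their 50-base words with other genes, so their counts cannot be assigned to 1 copy with certainty. Creb5, Hecw2, Gm4610, Fer1l6 and Car6 were the others among the 8 largest falls. Only 1 GFP-DUSP6 group was compared with 1 GFP group. A response to the plasmid DNA that differs between these groups cannot be told apart from an effect of DUSP6. This holds for every list of this contrast.

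Genes of DNA replication and mitosis were higher in the same libraries, by small amounts. Of 23 DNA replication genes 18 were higher and 0 lower (adjusted p = 0.0231), and of 22 mitosis genes 19 were higher and 0 lower (adjusted p = 0.0231, Fisher's exact test). Mcm3, a subunit of the replicative helicase, changed by 0.65 ± 0.06, Rrm1 by 0.66 ± 0.07, Mki67 by 0.60 ± 0.09 and Top2a by 0.49 ± 0.07 (log2, SE). In the edgeR refit without GFP-DUSP6 replicate 1, 2 and 3 and GFP replicate 3, 12, 11, 9 and 12 mitosis genes and 16, 16, 12 and 14 DNA replication genes were higher, against 18 and 18. Scaling over the listed genes takes most of them as unchanged, although they were listed for their p and 73.6% of the calls were higher. It shifted log2 fold changes by a median of -0.32 (TMM), where the called genes had a median of 0.35. Genes selected for their p and mostly higher would give such a shift, and so would an offset of the size factors. The shift is thus no test of the rises. With that scaling the refit passed 0 mitosis and 4 DNA replication genes. The direction of 6 called mitosis genes and 1 DNA replication gene flips with it, which are those whose rise was smaller than the shift.

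Of 25 ERK output genes 4 were lower (Areg, Dusp5, Spred2, Epha2) and 1 higher (Ier3; adjusted p = 0.032, Fisher's exact test), and of 9 MAP kinase phosphatases 3 were lower and 0 higher (Dusp5, Dusp1, Dusp8; adjusted p = 0.032). Areg, an EGF receptor ligand, changed by -0.62 ± 0.08 and Dusp5 by -0.69 ± 0.08, while Ier3 rose by 0.60 ± 0.08. Genes of the endoplasmic reticulum stress list were lower in 5 cases and higher in 1 (adjusted p = 0.0231), and 3 of the insulin and IGF list were lower (adjusted p = 0.032), a number of calls that did not pass the hypergeometric test (adjusted p = 0.158). In the edgeR refit 3 genes of the stress list and 2 of the insulin list were lower, and 1 and 1 without GFP-DUSP6 replicate 2, 1 and 0 without GFP-DUSP6 replicate 3, and 1 and 1 without GFP replicate 3. The ERK output list had 4 lower in that refit and 2 without any one of these 3 libraries, and the phosphatases 3, and 1 without GFP-DUSP6 replicate 1 or 3 or GFP replicate 3. With scaling over the listed genes by TMM and by median of ratios these 4 splits did not pass: the adjusted p was 0.944 and 1 for ERK output, 0.944 and 1 for the stress list, and 1 and 1 for the phosphatases and for the insulin list (Fisher's exact test). Under those scalings 22.7% and 21.9% of all calls were higher, so lists of mostly lower genes could hardly stand apart. Of 34 interferon genes 12 were higher and 1 lower, more calls than expected (hypergeometric adjusted p = 1.01e-08). The split did not pass the test (adjusted p = 0.219, Fisher's exact test). With median of ratios over the listed genes 4 were higher and 1 lower (adjusted p = 0.0303, Fisher's exact test), against that changed background. In the refit without GFP-DUSP6 replicate 3 or GFP replicate 3, 7 were higher, against 12. Adjusted over the list alone, 13 interferon, 19 NF-kB, 18 DNA replication, 19 mitosis, 5 ERK output and 3 phosphatase genes passed. The p53 list had 1 higher and 3 lower and NRF2 targets 3 and 0. In the edgeR refit 3 p53 genes were lower and 3 NRF2 targets higher, and 1 to 2 and 0 to 3 without single libraries. Heat shock genes had 0 higher and 2 lower, matrix 1 and 2 and hypoxia 0 and 2. The fatty acid synthesis, hepatocyte, histone and respiratory chain lists had 1 higher each. Gluconeogenesis, glycolysis, cholesterol synthesis, fatty acid oxidation, lysosome and ribosomal protein lists had 0 called members. Of the markers of other liver cells, Stab1 (endothelial) was higher by 1.11 ± 0.13; of the biliary markers 1 was higher and 2 lower, where Spp1 rose by 0.57 ± 0.08 and Krt19 and Sox9 had log2 fold changes of -0.39 ± 0.05 and -0.43 ± 0.08; 0 stellate and 0 macrophage markers were called.

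In total the authors' deposited table called 580 genes in this contrast, 4.61% of those tested, 427 higher and 153 lower (73.6% higher), of which 35 and 10 changed by at least 1 on the log2 scale. The edgeR refit passed 524 genes with the recovered size factors, 75.4% of them higher, and 198 with scaling over the listed genes (TMM), 22.7% of them higher. It passed 323, 304 and 193 without GFP-DUSP6 replicate 1, 2 and 3, and 264 without GFP replicate 3. List splits were lost when any one of 4 libraries was left out. Without any one of the 3 libraries labelled GFP-DUSP6, or without GFP replicate 3, 0 lists passed in the edgeR refit. In that refit 5 passed with all libraries, 7 without GFP replicate 1 and 5 without GFP replicate 2, against 7 from the deposited calls. A refit with a library fewer also has less power, so the loss cannot be traced to 1 library. The NF-kB list still had 16 or 17 members higher and 0 lower without each library. Of all calls 78.4% to 83.9% were higher without one of those 4. With TMM and median of ratios the NF-kB list had 13 higher and 0 lower (adjusted p = 7.57e-09 and 3.80e-09, Fisher's exact test). Through that scaling only 22.7% and 21.9% of all calls were higher, so these smaller p-values are no added support. By number of calls (hypergeometric adjusted p) the interferon, NF-kB, DNA replication, mitosis, stress (0.00564), ERK output (0.0243), phosphatase (0.0275), biliary (0.0332) and p53 (0.046) lists passed.

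In the siDUSP6 libraries interferon genes rose far more than any other list. Of 34 members 32 were higher and 0 lower (Fisher's exact adjusted p = 1.39e-08, where genes are not independent replicates). Irf7, a transcription factor of the interferon response, rose from 12.2 ± 4.64 to 1723 ± 360 normalized counts (SD, n = 3), a log2 fold change of 7.14 ± 0.24 (SE). Usp18 rose by 6.46 ± 0.26, Oas1a by 4.44 ± 0.17 and Bst2 by 2.91 ± 0.13. Among the 8 largest rises were Oas2 (8.15 ± 0.35), Oasl2 (8.05 ± 0.35) and Ifi44 (7.43 ± 0.34). The similar genes Apol9b (8.93 ± 0.34) and Apol9a (7.92 ± 0.39) share 21.0% and 13.1% of their 50-base words with other genes. Counts in the NC libraries were near 0 (Oas2 5, 0 and 3, Oasl2 3, 6 and 1, Ifi44 3, 6 and 2, Apol9b 0, 3 and 3, Apol9a 3, 0 and 9). The size of these folds is thus imprecise, and Oas2 ranged from 7.62 to 8.93 without single libraries. Ddx60 had 171 counts against 0 in NC, at least 57-fold higher against a floor of 3 counts over the group. Phf11d had 250 counts against 1 (ratio 250, 95% exact binomial interval 44.5 to 9913) and Oas1g 470 against 3 (ratio 157, interval 53.3 to 762); the intervals cover counting error only.

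The called genes of mature hepatocytes and of mitosis were lower with siDUSP6. Of 32 hepatocyte genes 8 were lower and 0 higher (adjusted p = 0.0197, Fisher's exact test), but the number called did not pass the hypergeometric test (adjusted p = 0.303). In the edgeR refit the split had an adjusted p of 0.0148, and of 0.16 with TMM, 0.258 with median of ratios and 0.0556 without NC replicate 3 (Fisher's exact test); 5 genes were lower without siDUSP6 replicate 2, against 8. Alb, which encodes albumin, went from 673.8 ± 94 to 170.8 ± 38.2 normalized counts (SD, n = 3), a log2 fold change of -1.98 ± 0.16 (SE), and Ttr had one of -1.93 ± 0.26. Atoh8 (-3.34 ± 0.28), Aqp1 (-2.55 ± 0.28), Aldh1a7 (-2.14 ± 0.23), Slco1a6 (-2.04 ± 0.25), Mme and Slc6a18 were the other large falls. Of 22 mitosis genes 19 were lower and 0 higher (adjusted p = 8.67e-06), among them Bub1b (-0.72 ± 0.08), Ccna2 (-0.62 ± 0.08) and Ccnb1 (-0.63 ± 0.09).

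The split of the other lists did not pass the test. Of the DNA replication genes 5 were lower and 0 higher (adjusted p = 0.107), with Rrm2 at -0.87 ± 0.07. Of the ERK output genes 7 were higher and 1 lower (adjusted p = 0.167), with Dusp5 at 0.78 ± 0.10 and Etv4 at 0.44 ± 0.08. MAP kinase phosphatases were higher in 6 cases and lower in 1, Dusp1 (adjusted p = 0.241). By number of calls (hypergeometric adjusted p) the phosphatases (0.000436) and hypoxia targets (0.0192) passed beside the interferon and mitosis lists. In the edgeR refit hypoxia targets had 2 higher and 4 lower, and 1 and 1 without siDUSP6 replicate 2. Cholesterol synthesis had 7 higher and 1 lower (adjusted p = 0.167), fatty acid oxidation 0 and 5 (adjusted p = 0.107), lysosome genes 6 and 0 (adjusted p = 0.111) and NRF2 targets 1 and 4 (adjusted p = 0.353). These counts changed when single libraries were left out, where the refit also has less power. In the edgeR refit 6 cholesterol synthesis and 5 lysosome genes were higher, and 0 and 0 without siDUSP6 replicate 2 or 3, 1 and 0 without NC replicate 2, 5 and 1 without siDUSP6 replicate 1, and 6 and 3 without NC replicate 3. When single libraries were left out of it, 3 to 5 ERK output genes and 2 to 4 phosphatases were higher, and 2 to 4 genes of fatty acid oxidation and 2 to 5 of DNA replication were lower. The NF-kB list had 5 higher and 0 lower (adjusted p = 0.167), p53 targets 3 and 4, endoplasmic reticulum stress 1 and 5, matrix 5 and 3, hypoxia 4 and 4, lipid droplet genes 3 and 1, fatty acid synthesis 1 and 3, glycolysis 1 and 2, insulin and IGF 1 and 2, and the respiratory chain 2 and 5. In the refit 4 NF-kB, 5 matrix and 3 p53 genes were higher, and 1 to 4, 1 to 4 and 1 to 3 without single libraries; 4 respiratory chain genes were lower, and 1 to 5 without single libraries, with the lowest of each without siDUSP6 replicate 2. Adjusted over the list alone, 32 interferon, 19 mitosis, 8 hepatocyte, 5 DNA replication and 8 ERK output genes passed. Fdps rose by 0.41 ± 0.09, Ppara had a log2 fold change of -0.97 ± 0.15 and Gclm of -0.78 ± 0.07. Markers of stellate, endothelial and macrophage cells had 0 calls; among biliary markers Sox9 was higher by 0.78 ± 0.08, and Spp1 and Anxa13 were lower.

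The authors' deposited table called 1959 genes in this contrast, 15.0% of those tested, 1017 higher and 942 lower, of which 195 and 83 changed by at least 1 on the log2 scale. The edgeR refit with all libraries passed 1593 of them, and between 669 (without siDUSP6 replicate 2) and 1389 when a single library was left out, with 789 without siDUSP6 replicate 3 and 940 without NC replicate 2. Of the deposited calls 51.9% were higher, and in the edgeR refit 53%, or 39.7% with scaling over the listed genes (TMM) or 33.8% (median of ratios).

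**Figure D2:**
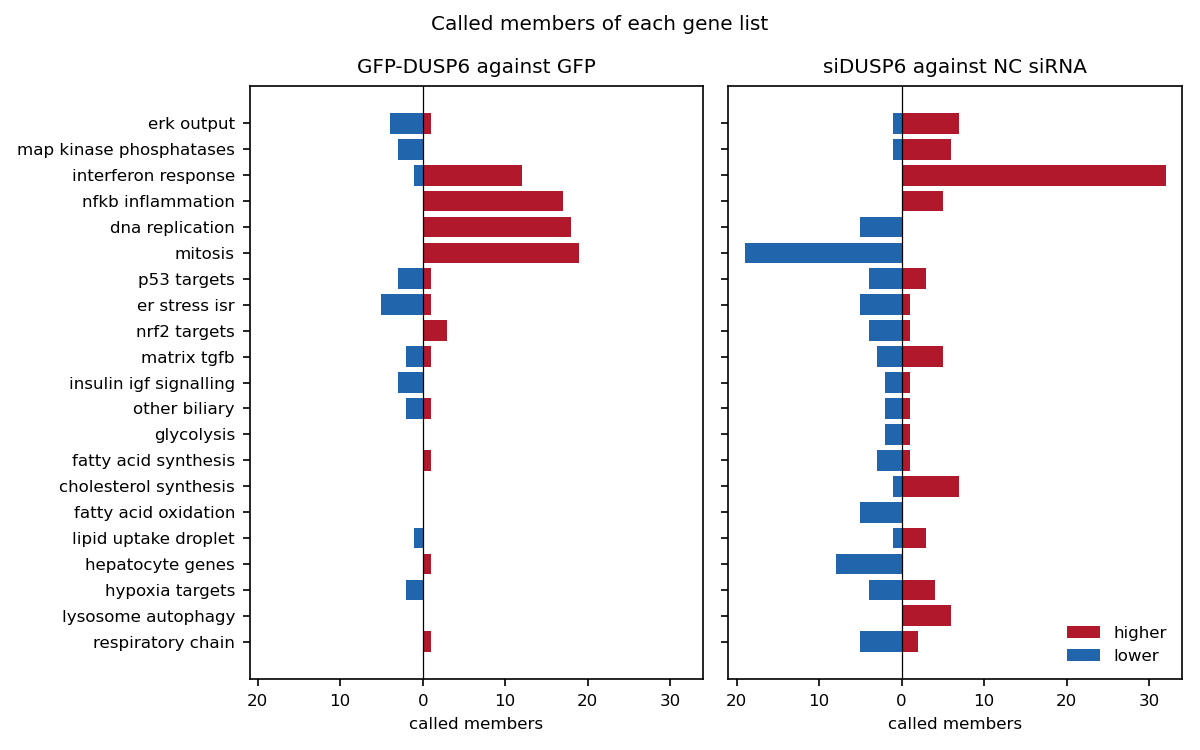
Called members per gene list (horizontal axis, number of genes; red to the right, higher; blue to the left, lower) for the lists with at least 3 called members in a contrast. The interferon list had 32 higher members with siDUSP6, and the mitosis list 19 higher with GFP-DUSP6 and 19 lower with siDUSP6.

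Both contrasts called 250 genes, against 90.2 expected from independent lists. That expectation takes 12592 genes as tested in both contrasts and as equally likely to be called. The excess alone is thus no measure of a shared response. Of the 250 genes 183 moved in opposite directions (73.2%) and 67 in the same direction. If the labels of the plasmid groups were exchanged, 67 would be opposite and 183 the same. With GFP-DUSP6 higher and siDUSP6 lower there were 132 genes (31.9 expected), with the reverse 51 (12.4 expected), both higher 54 (34.5 expected) and both lower 13 (11.4 expected); Fisher's exact test on this table gave p = 1.69e-12, where genes are not independent replicates. The share depended on the genes included and on scaling. Without the interferon list it was 76.8% of 237 genes. Of the 15 genes with a log2 fold change of at least 1 in each contrast 20% were opposite, where 9 of the 15 are interferon list genes that moved the same way and 3 of the other 6 were opposite. With scaling over the listed genes (TMM) the share in the edgeR refit was 61.3% of 62 genes (Fisher's exact p = 0.759). With the recovered size factors it was 71.2% of 205 genes. The TMM scaling takes genes selected as changed as unchanged, so it is no test of the share. Of the genes of DNA replication and mitosis called in both, 21 were opposite and 0 the same. Of the interferon genes 12 moved the same way and 1 opposite. With exchanged plasmid labels the counts of these lists would be reversed too.

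Cp, which encodes ceruloplasmin, had log2 fold changes of 0.71 ± 0.08 with GFP-DUSP6 and -1.33 ± 0.09 with siDUSP6. Itga1 had 0.94 ± 0.18 and -1.45 ± 0.24, and Hp 1.09 ± 0.17 and -1.25 ± 0.36. Without single libraries Hp ranged from -1.46 to -0.81 with siDUSP6. Fer1l6 had -0.87 ± 0.13 and 1.16 ± 0.09, and Dusp5 -0.69 ± 0.08 and 0.78 ± 0.10. Muc5b, Gm4610 and Fbxo5 complete the 8 opposite genes named by the rule. Nectin4 and C1ra (opposite) and Oas2 and Mx2 (same) had larger changes but a mean below 50 in a contrast; these 4 were named after their values were seen. In the same direction, Cxcl10 rose by 2.63 ± 0.40 and 4.90 ± 0.38, Ccl2 by 3.33 ± 0.08 and 1.59 ± 0.15, Usp18 by 1.55 ± 0.31 and 6.46 ± 0.26 and Rsad2 by 1.36 ± 0.26 and 6.59 ± 0.29. Dusp6 itself was lower in each contrast.

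**Figure D3:**
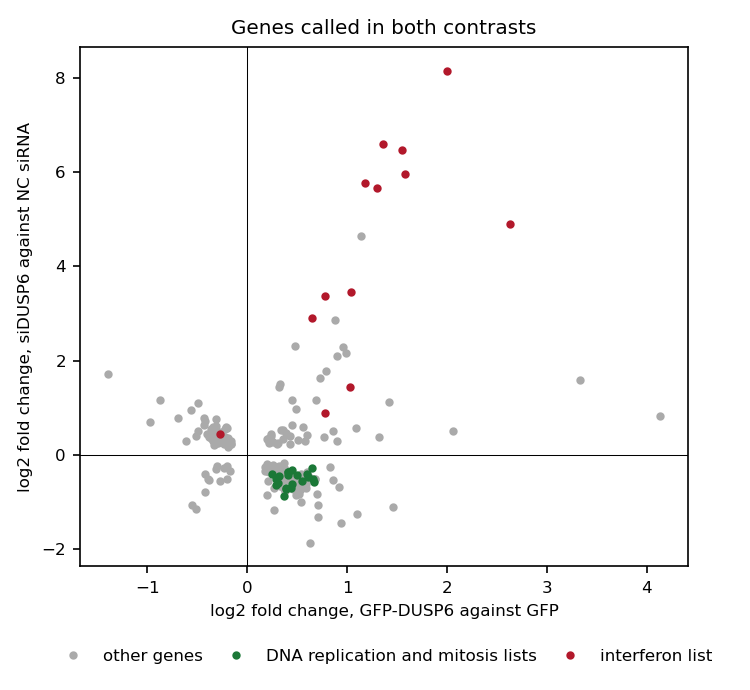
Log2 fold change with siDUSP6 (vertical axis) against that with GFP-DUSP6 (horizontal axis) for the 250 genes called in both contrasts; each point is a gene. Genes of DNA replication and mitosis lie at the lower right, and 12 interferon genes in the upper right.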

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

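Some listed genes had no adjusted p and were therefore outside the comparisons, yet had counts in the treated libraries and 0 in the 3 control libraries: 23 genes in the plasmid contrast and 36 in the siRNA contrast. The reverse, 0 in the treated libraries, held for 14 and 16 genes. In the siRNA contrast Tnfsf10 had 37 counts and Gbp6 34, at least 12.3-fold and 11.3-fold higher against a floor of 3 counts over the group, and Gbp10 had 28. These 3 genes were chosen after their values were seen. The listed genes were selected on their p, so a gene at 0 in 1 group is more frequent among them than among all genes, and the counts of such genes are no test.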

How the results depend on the processing

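Alternatives could end calls but not add any, since only selected genes are listed; the refit with recovered size factors, the hypergeometric list test and the shares without interferon genes were chosen after the data were seen. Set tests with a preset or estimated correlation were not run, and pseudocounts for normalized values did not apply. Dusp6 kept its direction and its side of the threshold under every refit. The 580 deposited calls of the plasmid contrast became 359 at a threshold of 0.01 and 45 with a log2 fold change of at least 1. The edgeR refit with recovered size factors passed 524; against that, 198 passed with TMM and 196 with median of ratios over the listed genes, and 193 to 497 without single libraries. The share of higher genes was 75.4% in that refit, 22.7% with TMM and 21.9% with median of ratios, through the shift given below. The 7 list splits became 0 at 0.01, 0 with a log2 fold change of at least 1, and 5 in the edgeR refit; the refit passed 2 with TMM (NF-kB, DNA replication), 2 with median of ratios (NF-kB, interferon) and 0 to 7 without single libraries. In the siRNA contrast 1959 became 1247 at 0.01, 278 with a log2 fold change of at least 1 and 1593 in the edgeR refit, and 669 to 1389 in that refit without single libraries; its 3 list splits became 2 with a log2 fold change of at least 1, with TMM, with median of ratios and without NC replicate 3. By the hypergeometric test 9 lists passed in the plasmid contrast and 4 in the siRNA contrast. The opposite share was 20% with a log2 fold change of at least 1 (50% without the interferon list), 71.2% in the edgeR refit, 61.3% with TMM and 58.9% with median of ratios; it was 76.8% without the interferon list and 63.2% to 74.1% without single libraries. Scaling over listed genes assumes that most of them did not change, which their selection on p goes against. It shifted log2 fold changes by -0.32 (plasmid) and by -0.06 and -0.10 (siRNA). In the plasmid contrast it reversed Fads2 (-0.12 TMM, -0.13 median of ratios), Gsr (-0.11 and -0.11) and H1f0 (-0.12 and -0.13). Cox7a2 (-0.031 and -0.038) and Txn1 (-0.0066, median of ratios) were reversed there too. With the replicate number as a block all 580 and 1959 passed, more than without it, and the opposite share was 73.2%; the prior degrees of freedom were infinite (plasmid, 11.1 without) and 16.2 (siRNA, 7.09 without), so these counts are no evidence of stability. Same-numbered libraries correlated in their deviations by 0.35, 0.37 and 0.01 (plasmid) and by 0.36, 0.09 and 0.16 (siRNA). Different-numbered libraries correlated by -0.38 to 0.02 (plasmid) and by -0.27 to 0.15 (siRNA). A pairing of plasmid replicates 1 and 2 and of siRNA replicate 1 thus stays possible. The labels state no pairing, and the SE and leave-one-out counts come from the unpaired fit.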

Other observations

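The tests in this part were chosen after the results were seen, except that of length and GC content over both contrasts. The 5 gene lists of the first paragraph were also chosen then. Their p-values were adjusted over these 5 lists alone in each contrast. Lists chosen after the calls were seen give no independent support. Acute-phase and complement genes were higher in 7 cases and lower in 0 with GFP-DUSP6, among them C3 (2.06 on the log2 scale) and C1ra (1.46); with siDUSP6 6 were lower, including C1ra (-1.11), and 3 higher; neither split passed the test (adjusted p = 0.496 and 0.408, Fisher's exact test), while the number called passed with GFP-DUSP6 but not with siDUSP6 (hypergeometric adjusted p = 0.0140 and 0.277). Of 24 genes of class I antigen presentation 10 were higher and 1 lower with siDUSP6 (split adjusted p = 0.0303, Fisher's exact test; hypergeometric 0.000885), with Tapbp at 1.79. Of 160 genes of xenobiotic metabolism 13 were lower and 3 higher (adjusted p = 0.0303, Fisher's exact test), but so few were called that the list did not stand out by number (hypergeometric p = 0.975). ErbB ligands and receptors had 3 lower with GFP-DUSP6 and 3 higher with siDUSP6 (Areg, Erbb3, Btc; split adjusted p = 0.0905 and 0.408, hypergeometric 0.0366 and 0.492), and integrins 4 higher and 1 lower against 7 higher and 5 lower (split adjusted p = 1 and 0.776, hypergeometric 0.0208 and 0.000885).

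Dusp6 was lower in the libraries labelled GFP-DUSP6. Dusp6 is itself known to be induced by ERK, so a lower ERK output is a candidate explanation for a lower count of the cell's own transcript. The split of the ERK output list (Fisher's exact p = 0.0183 without Dusp6 among the other calls, 5 called genes) is the split already reported, with an adjusted p of 0.032 over the lists, and is no independent test of it. An exchange of the labels of the plasmid groups stays open too, since the log2 fold change of -0.51 does not separate the plasmid's transcript from that of the cell. The directions across contrasts do not settle it: Areg, Dusp5 and Dusp8 were lower with GFP-DUSP6 and higher with siDUSP6, but Ier3 rose and Dusp1 fell in both. Of the 250 genes called in both 183 were opposite, and 76.8% without the interferon list. With scaling over the listed genes the association was not detected (Fisher's exact p = 0.759). That scaling takes genes selected as changed as unchanged, so it is no test of the association. Reading the association as support for the labels presumes that gain and loss act in opposite directions.

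Interferon genes were higher with siDUSP6. The median log2 fold change of the called members, 4.86, lies far beyond any shift between scalings, which argues against scaling. A graded effect of the amount of DUSP6 stays open: 12 members were higher in the plasmid contrast too, but Dusp6 was counted lower in both. A response to the siRNA molecule that does not run through Dusp6 cannot be told apart from an effect of Dusp6. Only 1 siRNA group against Dusp6 was compared. The same limit holds for the lower mitosis and hepatocyte genes in these libraries. Whether those falls are linked to the interferon rise was not tested.

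Genes of DNA replication and mitosis were higher with GFP-DUSP6; with siDUSP6 the mitosis list was lower, while the split of the 5 called DNA replication genes did not pass (adjusted p = 0.107). That 21 of 21 called in both contrasts were opposite follows from these directions and adds no support, so opposite effects of gain and loss stay open, the more as Dusp6 was counted lower in both. At most 7.19% of the tested genes were called in the direction of the lists in a contrast. That share cannot exclude a small scaling offset, since only 4.61% (plasmid) and 15.0% (siRNA) were called in either direction. Scaling over the listed genes left 0 mitosis genes past the threshold in the plasmid contrast and 19 in the siRNA contrast. It rests on genes selected as changed, so it does not settle the question. In the siRNA contrast the lists still stood apart from 10000 random lists of called genes after a linear fit on gene length and GC content (one-sided permutation p = 0.0015), which argues against these as the whole cause there, while the difference of medians went from -0.74 to -0.45 (SD of random lists 0.27 and 0.17). For the plasmid part they stay open. The lists no longer stood apart after the fit (permutation p = 0.0918, from 0.0336), which met the criterion set beforehand for length or GC content as the cause. The difference of medians hardly moved, from 0.10 to 0.09, and the call ended as the SD of the random lists rose from 0.05 to 0.08; weighing this change was added after the result was seen.

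For the number of genes past the threshold, the 10 splits of 6 libraries are too few for a share under 0.05. The genes counted are those listed, which were selected on the real split, so that split was bound to give the most. It was 1 of 10 with as many genes in each contrast and gave 524 in the plasmid contrast against at most 1 in another split, and 1593 in the siRNA contrast against at most 0.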
